A study of Mus musculus with 8 samples.

How the data were processed

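Total RNA from 8 mouse tumors was measured on Affymetrix Mouse Gene 1.0 ST arrays, which carry probes along the exons of each transcript. Each tumor had 1 array, and per the labels' protocols no samples were pooled. Tumor tissue was frozen and homogenized, and RNA was extracted, amplified into sense-strand cDNA, fragmented and labelled with biotin, per the labels' protocols and the series' design text. The RNA came from whole tumor tissue, so each value averages over tumor cells and all other cells in the sample.

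The deposited values are log2 expression values per probe set that the authors made by robust multi-array averaging (RMA), per the series' design text. RMA corrects each array for background, makes the distributions of all arrays alike by quantile normalization, and summarises the probes of a probe set on the log2 scale. The design text names the affy package of Bioconductor 2.4, and the submitters' processing notes name affy and R 2.15.3. The chip description file is not given in the sources used here. Because RMA makes the arrays alike, a change in the total amount of RNA per tumor cannot be seen in these values. A log2 difference of 1.0 is a change of signal by a factor of 2.0, and RMA tends to understate the change of genes near background.

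The table held 34760 probe sets, and 34738 had a mean of at least 4.0 over the 8 arrays, the study's own expression limit. The other 22 were left out. Gene names came from the platform annotation given with the data: 21640 probe sets listed 1 gene symbol, 1321 listed several and 11799 listed none. Symbols were checked by Entrez ID against a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and did not list the ID of 87 probe sets. No coordinates are given, because no genome build is stated for the array annotation. For gene-level results each of 19937 genes was represented by the single-symbol probe set with the highest mean over all arrays. A probe set with several symbols named no gene.

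Samples were grouped by their titles as nonirradiated (4 tumors) or preirradiated (4 tumors). The comparison was preirradiated minus nonirradiated, fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), the moderated test the design text names. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over the 34738 probe sets. The study's own filter, an unadjusted p of at most 0.05 with a log2 change of at least 0.4 in size and a mean of at least 4.0, was applied to the same fit. The change limit was read as holding in either direction.

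Before the data were examined, 25 gene lists were fixed for pathways and for cell types that a mammary tumor sample can hold, including muscle, fat, skin and blood. Each was tested with camera in limma at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 25 lists. Camera asks whether the genes of a list moved differently from all other named genes. The same lists were tested with the correlation estimated from the data, with fry, and by an exact two-sided permutation test of list means over the 70 assignments of 8 tumors to 4 and 4. List members without a probe set of their own were not analysed here. Only Btg2 and Kit stand in 2 lists.

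The genes named were also chosen by a rule fixed before the data were examined. It takes 12 genes in each direction, first the largest changes past the adjusted threshold and the study's filter, then those past the study's filter in order of unadjusted p. Predicted genes, clone names, small RNAs, olfactory receptors and receptor segments were left out. The rule adds 5 genes named in publication titles that the design text cites, and up to 4 members of each list: the 2 with the smallest p and the 2 with the largest change. Genes named outside this rule are said to be so.

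The pipeline was tested on simulated data. With 200 of 34760 probe sets changed in simulated arrays of the same means and spreads, limma recovered 73.1% of changes of 0.5, 91.0% of changes of 1.0 and 90.9% of changes of 2.0 at the adjusted threshold. In that simulation 12 unchanged probe sets also passed the adjusted threshold and 149 passed the study's filter. Recovery at the adjusted threshold depends on the number and size of the changes put in, so it does not carry over to the real tumors. In 10 simulations with no change at all, a mean of 153.3 probe sets passed the study's filter and 0 passed the adjusted threshold. Probe sets were simulated as independent of each other, which those of real arrays are not.

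Alternatives covered the expression limit, the variance model, a further quantile normalization, centring of each array on its median, array weights, the replicate number of the titles as a block, 1 probe set per gene, the thresholds, the list test, and leaving out each tumor in turn. After the data had been seen, 3 further settings were added: leaving out both tumors high in skeletal muscle genes, a covariate for those genes, and leaving out low-numbered probe sets that list no gene. Array files hold no sequencing depth, and the number of arrays limits the precision. Plots were drawn with matplotlib 3.10.9.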

Results

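Gene expression was profiled in 8 tumors grown from 4T1 cells, a mouse mammary carcinoma line that forms invasive and metastasizing tumors after transplantation into BALB/c mice. The cells were implanted into the fourth mammary gland. For 4 tumors this gland had been irradiated locally with 20 Gy of X-rays before the cells were placed (preirradiated), and for the other 4 it had not (nonirradiated). All tumors had grown for 18 days. The comparison asks how tumor tissue that arises in an irradiated bed differs in its transcripts from tumor tissue of an untreated bed, a model of local relapse after radiotherapy. Values are log2 RMA signals, given as mean ± SD over the 4 tumors of a group. The labels do not say whether each tumor came from a separate mouse. The limma, fry and permutation p-values therefore measure the spread between these tumors. Camera p-values at the preset correlation compare list genes with other genes and treat list genes as nearly independent, in every setting. Correlations estimated from the data ran from -0.11 (lymphatic endothelium) to 0.96 (skeletal muscle). Where the estimate exceeds the preset value, these camera p-values overstate the evidence.

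No gene passed correction for multiple testing. The genes ranked here are those past the study's filter, with predicted genes and the other classes of the rule left out. Among them, several matrix and contractile genes, which were higher in preirradiated tumors, and chromogranin A, which was lower, had the smallest p. Col5a2 (probe set 10354309), a chain of the fibrillar collagen V, was 7.94 ± 0.15 in preirradiated and 7.39 ± 0.07 in nonirradiated tumors (n = 4 each), a log2 difference of 0.55 (SE 0.074) or 1.46-fold. Tnc (probe set 10513739), the matrix glycoprotein tenascin C, was 11.58 ± 0.15 against 10.95 ± 0.12, or 1.55-fold. Mfap5, a microfibril protein, was 1.69-fold higher and Col1a2, a chain of collagen I, was 1.45-fold higher. Loxl1, which crosslinks elastin and collagen, was 1.47-fold higher. Srpx2, a secreted sushi-repeat protein, was 1.66-fold higher, the metalloprotease Adam12 1.39-fold and the carboxypeptidase-like Cpxm2 1.40-fold. The actin-associated Tagln and the smooth muscle actin Acta2 were 1.39-fold and 1.34-fold higher. Tnnt2, the cardiac form of troponin T, was 10.33 ± 0.26 against 9.65 ± 0.09, and Ptprn, a receptor-type phosphatase of secretory granules, was 1.33-fold higher. In each of these 12 genes all preirradiated tumors lay above all nonirradiated tumors.

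Among the genes that were lower, Chga (probe set 10397882), the secretory granule protein chromogranin A, was 7.34 ± 0.22 in preirradiated and 8.11 ± 0.09 in nonirradiated tumors (n = 4 each), a log2 difference of -0.77 (SE 0.10). Timd4, a phosphatidylserine receptor of macrophages, was 6.17 ± 0.13 against 6.72 ± 0.19. Mgl2, a C-type lectin of macrophages and dendritic cells, was 8.05 ± 0.20 against 8.62 ± 0.21. The chemokines Ccl24 and Ccl12 differed by -0.60 (SE 0.17) and -0.51 (SE 0.15). Prf1, the pore-forming perforin of cytotoxic lymphocytes, was 7.14 ± 0.10 against 7.96 ± 0.57, and nonirradiated tumor 2, at 7.12, lay within the preirradiated range. The remaining genes of the rule were the nuclear receptor Nr2f1 (-0.44), the cytochrome P450 Cyp1b1 (-0.53), the schlafen gene Slfn1 (-0.50), the glutathione transferase Gsta4 (-0.48), the sodium pump subunit Atp1b1 (-0.41) and the scramblase Plscr2 (-0.50). The groups overlapped for Ccl24, Ccl12, Atp1b1, Prf1 and Plscr2.

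With limma, 0 of 34738 probe sets passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.544. At an unadjusted p under 0.05 there were 2015 probe sets (985 higher, 1030 lower), where 1736.9 would be expected by chance. Some other splits of the tumors into 4 and 4 gave more, up to 3787, so this excess does not set the real grouping apart. The study's own filter, which has no correction, was passed by 223 probe sets, 170 higher and 53 lower. Simulated arrays without any change, with probe sets drawn independently, gave a mean of 153.3. Genes of real arrays move together. Of 35 splits of the tumors into 4 and 4, the real one included, 7 gave at least 223. Of the 223, 97 stood for named genes (69 higher, 28 lower), 114 listed no gene (97 higher, 17 lower) and 12 were others. Of the 97 named genes, 53 had groups that did not overlap (45 higher, 8 lower), but the filter itself favours such genes. Over all tested probe sets 3.36% did not overlap (581 higher, 585 lower), where chance gives 2.86%. The 24 genes described above passed the study's filter, and their limma adjusted p was at least 0.595. Ptprn, Acta2, Nr2f1, Slfn1, Gsta4, Ccl12, Atp1b1 and Plscr2 missed that filter in 1 or more alternative settings, and the other 16 passed it in all 19. Leaving out 1 tumor brought Atp1b1 to -0.34 (nonirradiated 4), -0.36 (preirradiated 3) or -0.37 (nonirradiated 1), and Slfn1 to -0.37 (preirradiated 1). It brought Ptprn to 0.37 (preirradiated 2) or 0.39 (nonirradiated 2, preirradiated 1), and Acta2 to 0.38 (nonirradiated 2, preirradiated 1). It brought Nr2f1 to -0.38 (preirradiated 1) or -0.39 (preirradiated 3, nonirradiated 4), Gsta4 to -0.38 (nonirradiated 4, preirradiated 3), and Ccl12 to -0.399 (preirradiated 3). The number of named genes fell to 60 without preirradiated tumor 1 and to 58 without both preirradiated tumors 1 and 3. It was 196 without preirradiated tumor 2 and 188 without preirradiated tumor 4. Its balance depended on the setting, with 51 higher and 36 lower when each array was centred on its median and 150 higher and 24 lower with array weights.

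**Figure D1:**
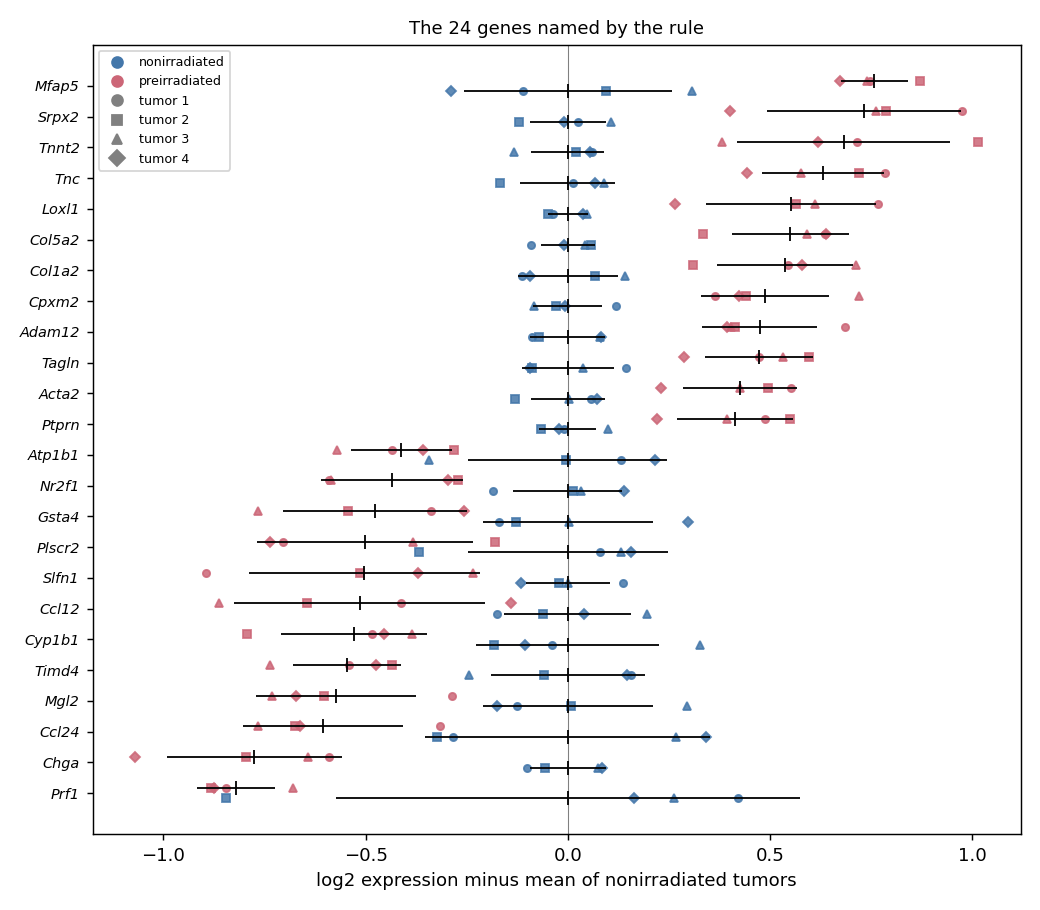
Log2 signal of the 24 genes chosen by the fixed rule in each tumor, relative to the mean of the nonirradiated tumors, with points for the 4 nonirradiated and 4 preirradiated tumors and bars for mean ± SD. The 12 genes on the higher side do not overlap between groups, and Ccl24, Ccl12, Atp1b1, Prf1 and Plscr2 on the lower side do.

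Genes of fibroblasts and matrix rose together in preirradiated tumors. Of 23 measured members 22 were higher, with a mean difference of 0.37, and all 4 preirradiated tumors had a higher list mean than any nonirradiated tumor (camera adjusted p = 1.2e-21; adjusted p = 0.115 with an estimated correlation). Lox, the lysyl oxidase that crosslinks collagen, was 9.49 ± 0.32 against 8.69 ± 0.44, beside Mfap5 (0.76), Tnc (0.63) and Col5a2 (0.55) on the log2 scale. In this list 8 members passed the study's filter, all higher, 12 passed when adjusted over the list alone, and 0 passed over all genes. The pericyte and smooth muscle list rose as well, with 11 of 12 members higher, a mean difference of 0.32 and 4 of 4 preirradiated tumors above all nonirradiated tumors (camera adjusted p = 3.1e-07; adjusted p = 0.115 with an estimated correlation). Tagln, Acta2, Myh11 and Cnn1, the last 2 named after their values were seen, passed when adjusted over the list alone. Des, the muscle intermediate filament desmin, was 8.20 ± 2.49 against 6.31 ± 0.13, with preirradiated tumors 1 and 3 at 9.17 and 11.3 and the others at 6.15 and 6.19. Des differed by 1.89, or 0.86 without preirradiated tumor 3, and without Des the mean difference of the other 11 pericyte genes was 0.18. The same tumors had the highest means of the fibroblast list, 9.72 and 9.64, against 9.42 and 9.40 in preirradiated tumors 2 and 4 and at most 9.30 in nonirradiated tumors. Without tumors 1 and 3 the fibroblast list difference was 0.23 (camera adjusted p = 2.6e-10) and the pericyte list difference was 0.11 (camera adjusted p = 0.00186).

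Skeletal muscle genes were very high in preirradiated tumors 1 and 3 and not in the other preirradiated tumors. The mean of the 19 genes lay 2.42 and 3.69 above the nonirradiated mean in these tumors, and -0.051 and 0.067 from it in preirradiated tumors 2 and 4. All 19 members were higher on average, by a mean of 1.53 (camera adjusted p = 4.5e-10; adjusted p = 0.398 with an estimated correlation), but 0 passed the study's filter and 0 passed when adjusted over the list alone. Myl1, a fast-muscle myosin light chain, was 7.63 ± 3.24 against 4.86 ± 0.12. Atp2a1, the calcium pump of fast muscle, was 8.64 ± 3.22 against 5.93 ± 0.16. The list rested on these tumors: its difference was 0.0083 without both (camera adjusted p = 0.963), and 0.81 without preirradiated tumor 3 alone, where Myl1 differed by 1.73 and Atp2a1 by 1.60.

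Adipocyte genes followed the same tumors in part. The list rose, with 16 of 17 members higher and a mean difference of 0.42 (camera adjusted p = 1.5e-04; adjusted p = 0.482 with an estimated correlation), and preirradiated tumors 1 and 3 stood 1.26 and 0.32 above the nonirradiated mean. Car3, a carbonic anhydrase of fat and muscle, was 9.63 ± 2.07 against 7.44 ± 0.78, and Plin4, a lipid droplet protein, was 6.40 ± 0.53 against 5.86 ± 0.10. Both passed the study's filter and 0 members passed when adjusted over the list alone. Car3 missed the filter without any of 5 of the 8 tumors, down to 1.54 without preirradiated tumor 1, and Plin4 without any of 6, down to 0.39 without preirradiated tumor 1 or 3. Without preirradiated tumor 1 the difference was 0.14 (camera adjusted p = 0.269). Endothelial genes rose, with 18 of 24 members higher by a list mean of 0.087 (camera adjusted p = 0.00219; adjusted p = 0.487 with an estimated correlation). Vwf, von Willebrand factor, differed by 0.33 (SE 0.095), and the angiopoietin receptor Tek by 0.31 (SE 0.10). No more than 1 preirradiated tumor, tumor 1, had a list mean above all nonirradiated tumors, and without it the difference was 0.034 (camera adjusted p = 0.222). It was 0.052 without nonirradiated tumor 1 and 0.13 without nonirradiated tumor 2. Lymphatic endothelium did not pass (6 genes, camera adjusted p = 0.090), although Pdpn, podoplanin, was 9.18 ± 0.48 against 8.57 ± 0.33 and passed the study's filter. Pdpn missed it without any of 5 of the 8 tumors, down to 0.41 without preirradiated tumor 3. Without preirradiated tumor 2 the lymphatic list passed narrowly (0.18, camera adjusted p = 0.0494). Red blood cell genes (4 measured, camera adjusted p = 0.410) and skin epidermis genes (7 measured, camera adjusted p = 0.535) did not pass. The skin list was highest in preirradiated tumor 3, at 6.32, and nonirradiated tumor 4, at 6.14. Without nonirradiated tumor 4 it passed as higher (0.20, camera adjusted p = 0.0154). Without preirradiated tumor 3 it differed by -0.14 and did not pass.

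**Figure D2:**
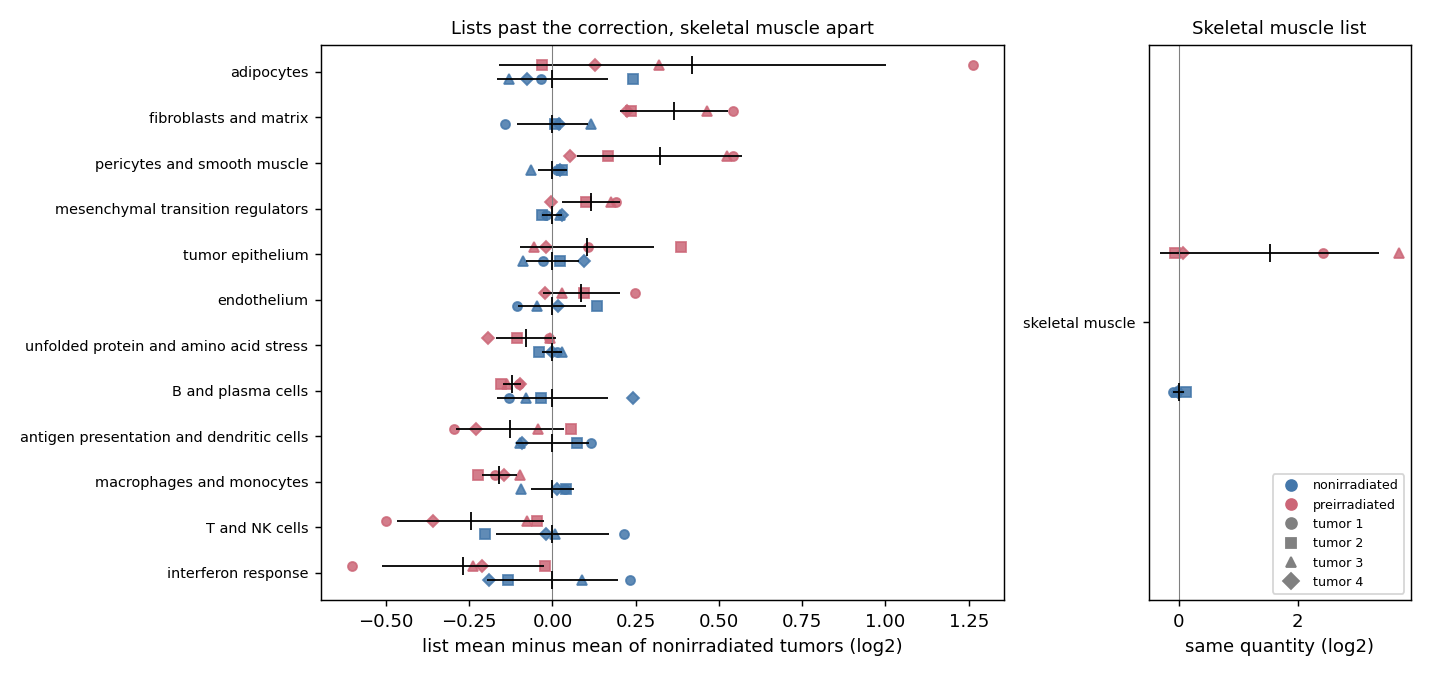
Mean log2 signal in each tumor of the 13 gene lists that passed camera, skeletal muscle in a panel of its own, relative to the mean of the nonirradiated tumors, with points for tumors and bars for mean ± SD of each group. The fibroblast and pericyte lists lie higher in all 4 preirradiated tumors, and the macrophage list lies lower in all 4, narrowly so in preirradiated tumor 3. The skeletal muscle list stands at 2.42 and 3.69 in preirradiated tumors 1 and 3.

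Macrophage and monocyte genes fell. All 21 measured members were lower, by a list mean of -0.16 (camera adjusted p = 2.8e-07, adjusted p = 0.115 with an estimated correlation). All 4 preirradiated tumors had a lower list mean than any nonirradiated tumor. The gap was narrow, with preirradiated tumor 3 at 10.041 and nonirradiated tumor 3 at 10.045. Folr2, a folate receptor of tissue macrophages, was 8.74 ± 0.44 against 9.27 ± 0.22 and was the only member past the study's filter, which it missed without any of 5 of the 8 tumors, with -0.31 without preirradiated tumor 2. C1qc, a chain of complement C1q, was 11.87 ± 0.07 against 12.05 ± 0.08. When adjusted over the list alone 0 members passed. Interferon response genes also fell, with all 21 members lower by a list mean of -0.27 (camera adjusted p = 6.1e-08; adjusted p = 0.398 with an estimated correlation), and 3 of 4 preirradiated tumors lay below all nonirradiated tumors. Gbp3, an interferon-induced GTPase, was 9.05 ± 0.52 against 9.64 ± 0.33, and the chemokine Cxcl10 was 9.61 ± 0.45 against 10.20 ± 0.48. In both, preirradiated tumor 1 stood apart on the low side, and without it the differences were -0.33 and -0.36. Oasl1 and Irf7, an antiviral gene and a transcription factor of the response, differed by -0.27 (SE 0.070) and -0.25 (SE 0.075). No interferon gene passed the study's filter or the adjustment over the list alone (0 of 21), and without preirradiated tumor 1 the list difference was -0.16 (camera adjusted p = 6.2e-05).

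T and NK cell genes fell, with 19 of 22 members lower by a list mean of -0.24 and 2 of 4 preirradiated tumors, 1 and 4, below all nonirradiated tumors (camera adjusted p = 4.1e-05; adjusted p = 0.383 with an estimated correlation). Besides Prf1, the T helper coreceptor Cd4 differed by -0.22 (SE 0.071), and the cytotoxic protease Gzmb was 7.70 ± 0.48 against 8.46 ± 0.81. Prf1 was the 1 member past the study's filter, and 0 passed when adjusted over the list alone. Without preirradiated tumor 1 the list difference was -0.16 (camera adjusted p = 0.00399). B and plasma cell genes fell, with 12 of 13 lower by a list mean of -0.12 (camera adjusted p = 0.00291; adjusted p = 0.482 with an estimated correlation). Bank1, a B cell adaptor, was 5.91 ± 0.21 against 6.32 ± 0.22 and passed the study's filter except without nonirradiated tumor 4 (-0.31), preirradiated tumor 3 (-0.34) or preirradiated tumor 2 (-0.36), while the B cell receptor component Cd79a was near background except in nonirradiated tumor 4, at 5.69. Without that tumor Cd79a differed by -0.041 and the list by -0.041 (camera adjusted p = 0.256). Antigen presentation and dendritic cell genes fell, with 15 of 17 lower by a list mean of -0.13 (camera adjusted p = 0.0104; adjusted p = 0.482 with an estimated correlation). Clec9a, a receptor of cross-presenting dendritic cells, was 5.34 ± 0.18 against 5.63 ± 0.24, and Ciita, the regulator of MHC class II genes, was 7.77 ± 0.57 against 8.12 ± 0.48. The Clec9a difference was -0.18 without nonirradiated tumor 1. The Ciita difference ran from -0.16 without nonirradiated tumor 1 to -0.62 without preirradiated tumor 2. The call of the list ended without nonirradiated tumor 1 (-0.089), nonirradiated tumor 2 (-0.10), preirradiated tumor 1 (-0.072) or preirradiated tumor 4 (-0.094), with each array centred on its median (-0.16, camera adjusted p = 0.0663) and with array weights (-0.095, camera adjusted p = 0.102).

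The other immune lists did not pass. Neutrophil genes had 14 of 20 members lower by a list mean of -0.049 (camera adjusted p = 0.425). Ngp, a granule protein of immature neutrophils, was 7.34 ± 0.38 against 7.88 ± 0.33 and passed the study's filter, but missed it without any of 4 of the 8 tumors (-0.38 without preirradiated tumor 1), while Mmp9, the gelatinase, was 11.18 ± 0.27 against 10.82 ± 0.24. Without nonirradiated tumor 3 the neutrophil list mean was higher, by 0.11, and did not pass. The list passed as lower without nonirradiated tumor 2 (-0.15) or preirradiated tumor 3 (-0.14), and without both preirradiated tumors 1 and 3 (-0.20). Mast cell genes (10 measured, camera adjusted p = 0.725) passed as lower only without both of these tumors (-0.10, camera adjusted p = 0.0285). Inflammatory cytokines and chemokines (26 measured, camera adjusted p = 0.977) went both ways: Il11, a cytokine of the IL-6 family, was 6.20 ± 0.06 against 5.95 ± 0.06 and passed when adjusted over the list alone, and the T cell chemokine Ccl5 was 8.21 ± 0.31 against 8.67 ± 0.20. Ccl5 passed the study's filter except without nonirradiated tumor 1 (-0.36), preirradiated tumor 1 (-0.36) or preirradiated tumor 4 (-0.37). The mean of that list was -0.016 while the sign of camera was positive, and without nonirradiated tumor 3 it passed as higher (0.063, camera adjusted p = 0.0439).

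Epithelial genes, which mark the carcinoma cells, rose, with 15 of 20 members higher by a list mean of 0.10 (camera adjusted p = 0.00356; adjusted p = 0.482 with an estimated correlation). Krt7, a simple-epithelium keratin, was 10.72 ± 0.13 against 10.33 ± 0.11 and passed when adjusted over the list alone, and Cldn7, a tight junction claudin, was 8.68 ± 0.19 against 8.40 ± 0.17. Preirradiated tumor 2 stood 0.39 above the nonirradiated mean, and without it the list difference was 0.010 (camera adjusted p = 0.375). Without preirradiated tumor 3 it was 0.16. Mesenchymal transition regulators, which fibroblasts also express, rose beside the fibroblast list (0.37), with 12 of 17 higher by a list mean of 0.12 (camera adjusted p = 0.00839; adjusted p = 0.398 with an estimated correlation). Prrx1, a homeobox factor of mesenchyme, was higher by 0.55 (SE 0.11), and it and the stromelysin Mmp3 (0.40, SE 0.16) passed the study's filter. Mmp3 missed it without any of 4 of the 8 tumors, down to 0.30 without preirradiated tumor 3. The call of this list ended without both tumors high in muscle genes (0.049, camera adjusted p = 0.135). Normal mammary gland genes did not pass (13 measured, camera adjusted p = 0.312), with the basal keratin Krt14 at 7.73 ± 0.44 against 6.87 ± 0.50 and Krt5 high in nonirradiated tumor 4 and preirradiated tumor 3.

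Of the stress and growth lists, unfolded protein and amino acid stress genes fell, with 17 of 18 lower by a list mean of -0.079 (camera adjusted p = 0.00971; adjusted p = 0.374 with an estimated correlation). Sdf2l1, an endoplasmic reticulum chaperone component, differed by -0.17 (SE 0.076), and Vldlr, a lipoprotein receptor, was the 1 member that was higher, by 0.30 (SE 0.14). Without preirradiated tumor 3 Vldlr differed by 0.15, and without preirradiated tumor 1 Sdf2l1 differed by -0.098. The call of the list ended without preirradiated tumor 2 (-0.070) or preirradiated tumor 4 (-0.041), and with either further scaling of the arrays. Hypoxia and glycolysis genes did not pass (29 measured, camera adjusted p = 0.483): Vegfa, the endothelial growth factor, differed by 0.29 (SE 0.13), with preirradiated tumor 1 above the rest at 9.93, and the hydroxylase Egln3 by -0.16 (SE 0.073). That list passed as higher without nonirradiated tumor 3 (0.074) or nonirradiated tumor 4 (0.071) and as lower without both tumors high in muscle genes (-0.078, camera adjusted p = 0.0132). Proliferation genes (28 measured, camera adjusted p = 0.483) did not pass, except without nonirradiated tumor 1, the tumor with the highest list mean, at 9.40 (difference 0.098, camera adjusted p = 8.0e-09). The estimated correlation of this list over all tumors was 0.67, above the preset value. The small p therefore counts genes that move together as nearly independent and is not strong evidence. No p with an estimated correlation is given for that setting. Neither p53 target genes (19 measured, camera adjusted p = 0.689) nor immediate early genes (16 measured, camera adjusted p = 0.701) passed. The p53 list had a median of -0.0049 and a mean of 0.0082, which ran from -0.015 to 0.025 when 1 tumor was left out. Immediate early genes passed as lower without preirradiated tumor 1 (-0.070, camera adjusted p = 0.0438).

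The design text cites work on the Kit ligand and its receptor and on CYR61 with the integrin alpha V beta 5 in this model, and these 5 genes differed little. Kitl, the Kit ligand, differed by -0.091 (SE 0.13), and Kit, its receptor, by -0.085 (SE 0.13). Ccn1, which encodes CYR61, differed by 0.013 (SE 0.14), the integrin subunit Itgav by 0.050 (SE 0.11) and Itgb5 by -0.031 (SE 0.068). The list did not pass (camera adjusted p = 0.734), and leaving out 1 tumor turned the signs of Ccn1 (-0.055 to 0.13), Kit (-0.20 to 0.022), Itgav (-0.030 to 0.13), Itgb5 (-0.075 to 0.0032) and the list mean (-0.078 to 0.012). Kitl ranged from -0.19 to -0.011.

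The arrays were close in level, with medians from 5.937 to 5.977 in nonirradiated and 5.982 to 5.996 in preirradiated tumors. Every preirradiated median thus lay slightly above every nonirradiated median. Correlations across probe sets between pairs of arrays ranged from 0.991 to 0.996, where probe sets are not independent replicates. The mean correlation was 0.995 within the nonirradiated group, 0.992 within the preirradiated group and 0.993 between groups. Along the first principal component, which held 27.9% of the variance, the groups differed by 18.1 (exact two-sided permutation test, p = 0.114, smallest possible p = 0.0286). Preirradiated tumors 3 and 1 lay highest on it, at 26.9 and 23.0. On this component preirradiated tumors 2 and 4, at -3.39 and -10.2, lay near the nonirradiated tumors, which ranged from -14.1 to -3.93. The second component held 23.05% of the variance, and on it preirradiated tumors 2 and 4 lay at opposite ends, at 21.47 and -20.74. Both lay outside the nonirradiated range there, which ran from -14.81 to 11.96. Preirradiated tumors 1 and 3, at 7.96 and -10.87, lay within it.

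In sum over the 25 lists, camera called 13, of which 7 rose and 6 fell. Without both tumors high in muscle genes 3 rose and 10 fell, and with the muscle genes as a covariate 3 rose and 8 fell. Without both tumors the endothelial (0.037), mesenchymal (0.049), adipocyte (0.049) and muscle (0.0083) lists were no longer called, and the neutrophil (-0.20), mast cell (-0.10), immediate early (-0.12) and hypoxia (-0.078) lists were called as lower. With the covariate the endothelial (0.059), mesenchymal (0.057) and adipocyte (0.16) lists were no longer called, the muscle list was not tested, and the neutrophil (-0.20) and immediate early (-0.092) lists were called as lower. Centring each array on its median left 11 called lists (7 higher, 4 lower), and a further quantile normalization and array weights left 12 each (7 higher, 5 lower). With an estimated correlation or fry, 0 lists passed after adjustment, and at an unadjusted p under 0.05 these tests had 3 and 4. The exact permutation test of list means could hardly pass in this design: 3 lists had its smallest possible p, and 15 of the 25 would have been needed. These were fibroblasts, pericytes and macrophages (exact permutation p = 0.0286 each), with a fry adjusted p of 0.0776. For macrophages this rests on the narrow gap between 10.041 in preirradiated tumor 3 and 10.045 in nonirradiated tumor 3. Of the 13 called lists, 7 passed without each tumor in turn.

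**Figure D3:**
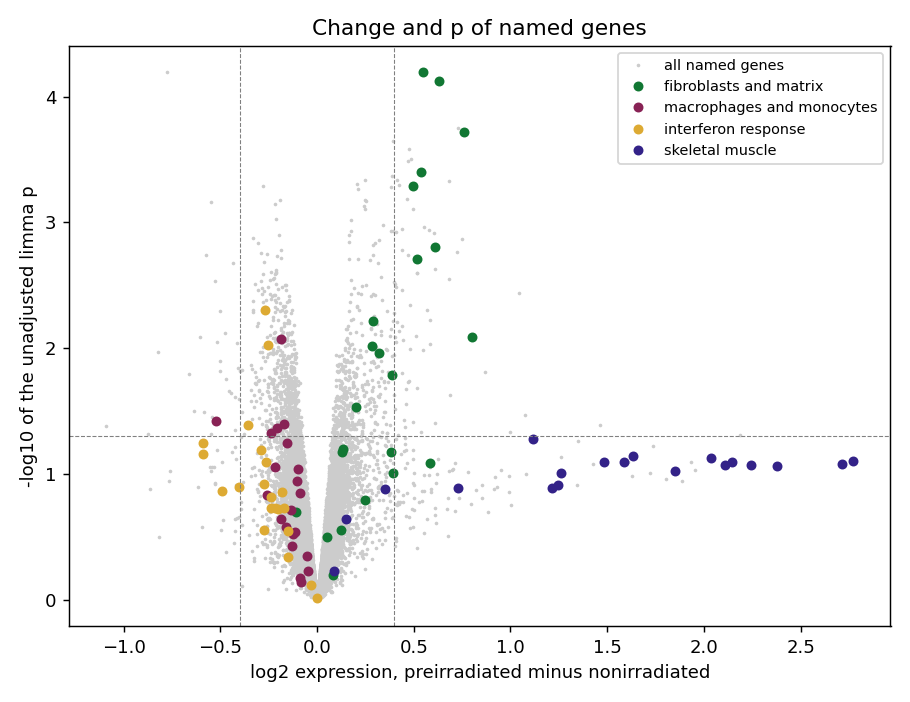
Log2 difference (preirradiated minus nonirradiated) against -log10 of the unadjusted limma p for each of 19937 named genes, with the fibroblast, macrophage, interferon and skeletal muscle lists coloured and dashed lines at p 0.05 and log2 changes of 0.4 in size. Of the 23 fibroblast genes 22 lie to the right, all 21 macrophage and all 21 interferon genes lie to the left, and most muscle genes lie far to the right, all below the p line.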

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

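All tests below except the count of splits for lists, for probe sets past the study's filter and for probe sets past the adjusted threshold were chosen after the result was seen. In 246 groups of 4 tumors, 22 had a tumor far from the other 3, where chance gives 12.3. Of these, preirradiated tumor 3 had 6, preirradiated tumor 1 had 5 and nonirradiated tumor 4 had 4.

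Preirradiated tumor 1 stood apart in Gbp3 (8.26), Cxcl10 (8.94) and Clec9a (5.06), all low, and in Vegfa (9.93) and Adam12 (7.39), both high. Preirradiated tumor 3 was high in the skin list (6.32) and in its members Krt10 (7.76), Krt77 (7.09) and Lce1a1 (6.03), as well as in Krt5 (6.93), and low in Cd79a (4.60). Nonirradiated tumor 4 was high in Krt5 (7.37), Lce1a1 (5.60), Cd79a (5.69) and the list of genes named in cited titles (9.85). Single tumors also stood apart in Col5a2 (preirradiated 2, low, 7.73), Aplnr (preirradiated 4, high, 8.74), Cd4 (preirradiated 4, low, 5.71), Plscr2 (nonirradiated 2, low, 6.45), Cma1 (nonirradiated 3, high, 5.14), Cenpe (nonirradiated 1, high, 8.74) and the pericyte list (nonirradiated 3, low, 7.50).

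The first pattern is the skeletal muscle signal of preirradiated tumors 1 and 3. All 19 of 19 muscle genes lay above every nonirradiated tumor in both, as muscle tissue in those samples would give. Atp2a1 reached 10.81 and 11.99 there against at most 6.16 in nonirradiated tumors. These tumors were picked by the mean of the same genes, so the count adds no support of its own. Muscle genes did not rise in every preirradiated tumor, since 2 lay at or below the highest nonirradiated list mean of 6.28. That is part of how the pattern was described and not a separate test of a cause. Whether tumors in irradiated beds more often take in body wall muscle, or these samples were taken with adjacent muscle, stays open, because 2 of 4 tumors cannot show it.

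The second pattern is the higher fibroblast and matrix list. Muscle-containing tissue in preirradiated tumors 1 and 3 is argued against as its whole cause: without them the difference was 0.228 (SE 0.0796). Of 23 genes, 10 lay above every nonirradiated tumor in both remaining tumors, where chance gives 1.53. These genes move together (estimated correlation 0.41), so they are not independent cases. With 4 tumors against 2 there are 15 assignments, so chance is not excluded. A lower share of tumor cells that raised all other cell types alike is argued against, since the macrophage list differed by -0.160 (SE 0.0414). A lower share with an uneven change of the other cells stays open. The epithelial list, which marks carcinoma cells, differed by 0.10, or by 0.010 without preirradiated tumor 2, and does not decide it. Other named genes of that signal level had a median change of -0.0219, beside 0.385 for the list, so the level as a whole did not move. Quantile normalization holds such medians near 0, so this cannot tell whether the arrays differed before it. Whether the fibroblasts of the irradiated bed changed or were more numerous was not tested and stays open.

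The third pattern is that 103 of the 223 probe sets past the study's filter carry low numbers and list no gene; on this array type such numbers are used for control probe sets, as background, and the annotation used here does not say which. Of these 103, 91 were higher, and 60.3% of all 6573 such probe sets were. At a mean of 5.5 to 8 named genes had a median change of -0.00036, beside 0.0920 for these probe sets, which named genes of that level did not share. Whether the arrays differed in background cannot be told from this, since quantile normalization holds the median of most probe sets near 0. The group as a whole cannot be told apart from tumor-to-tumor spread, since the per-tumor median differed by 0.0701 (exact two-sided permutation p = 0.2). No biological explanation was tested, and the count without these probe sets was 123.

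Chance cannot be excluded for the counts. Of the 35 splits of the 8 tumors into 4 and 4, 7 gave at least 223 probe sets past the study's filter (highest other 466), and 8 gave at least 13 lists (highest other 17). For probe sets past the adjusted threshold the comparison decides nothing, since all 35 splits give at least 0 (highest other 1). For the 97 named genes it was 2 of 35, and the other split, with 99, also keeps preirradiated tumors 1 and 3 together, as the real one does.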

How the results depend on the processing

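The settings that leave out both muscle-rich tumors, use a muscle covariate or drop low-numbered probe sets were chosen after the data were seen. The 24 genes chosen first by the rule kept their sign in all 19 alternatives, and 0 of the 13 called lists had a mean of the other sign in any. These genes and lists were picked by their p in the same arrays, so a turned sign was unlikely and the kept signs add little support. Over all genes and lists followed, these included, 39 of 1862 gene values and 32 of 424 list means changed sign. Probe sets past the adjusted threshold stayed at 0 in each setting, with the smallest adjusted p between 0.0589 and 0.878 when 1 tumor was left out. Probe sets past the study's filter numbered 102 with 1 probe set per named gene (fewer were tested), 5 at a log2 change of at least 1.0 (4 higher, 1 lower), 123 without the low-numbered probe sets, and 181 to 385 leaving out 1 tumor (335 without preirradiated tumor 2, 385 without preirradiated tumor 4). Centring each array on its median gave 191, with 121 higher and 70 lower against 170 and 53, and for named genes 51 and 36 against 69 and 28. Named genes past it numbered 174 with array weights (150 higher, 24 lower), 58 without both muscle-rich tumors, 61 with the muscle covariate and 60 to 196 leaving out 1 tumor (60 without preirradiated tumor 1, 196 without 2, 188 without 4). Called lists numbered 0 with an estimated correlation, 0 by fry and 0 by exact permutation, where 15 of the 25 lists at the smallest possible p would have been needed, and 11 to 15 leaving out 1 tumor. Group separation was 9.58 to 22.8 leaving out 1 tumor (exact permutation p 0.114 to 0.6). The 7 higher and 6 lower called lists became 3 and 10 without both muscle-rich tumors and 3 and 8 with the muscle covariate. The hypoxia list reversed to -0.0775 without both muscle-rich tumors. Where not named, the cause was not tested. Replicate numbers did not pair the tumors: the deviations of same-numbered tumors correlated at -0.075, -0.29, -0.088 and -0.18. With the replicate block 193 probe sets passed the study's filter, 13 lists were called and 0 probe sets passed the adjusted threshold. Genes near the background of about 5, such as Cd79a, Cma1 and Mmrn1, limit what a small difference can show.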

Other observations

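The genes and tests here were chosen after their values were seen. With a log2 change of at least 1.0 the study's filter left 5 probe sets: Car3 (2.18), Serpina3n (1.46), Prg4 (1.07), Lamb3 (1.04) and Gzmf (-1.09). Serpina3n, an acute-phase protease inhibitor, and Prg4, the lubricating proteoglycan of joints and tendon sheaths, were highest in preirradiated tumors 1 and 3 (10.03 and 10.06, and 7.77 and 7.61), the tumors high in muscle genes. Lamb3 and Lama3, chains of the basement membrane protein laminin-332, were higher in preirradiated tumors by 1.04 (SE 0.26) and 0.43 (SE 0.12), with Lamb3 at 7.89 or more there and at most 7.85 in nonirradiated tumors. Itga2, a collagen and laminin receptor subunit, was higher by 0.46 (SE 0.16). Single genes that were also higher were Grem1, a BMP antagonist, by 0.57, Lrrc15, a marker of activated fibroblasts, by 0.58, and Fgf2 by 0.40.

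Some single genes were lower. Gzmf, a granzyme of activated cytotoxic cells, was lower by a log2 change of -1.09 (SE 0.45), while nonirradiated tumor 2 was the lowest of its group in Prf1 and in each granzyme named here or tested below (Gzmb at 7.32, Gzmd at 7.50). Ccl6, Ccl9 and Ccl8, myeloid CC chemokines, differed by -0.34 (SE 0.12), -0.22 (SE 0.054) and -0.27 (SE 0.26). The mean of these 3 differed by -0.275 (exact two-sided permutation p = 0.0571, over 4 lists tested adjusted p = 0.229). The lectin Clec10a differed by -0.24 (SE 0.070). Beside Chga (-0.77), the other granins Chgb and Scg2 lay near background (5.31 and 5.17 in nonirradiated tumors), where a fall could not be seen.

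A candidate explanation for the lower Timd4, Mgl2, Folr2, Ccl24 and Ccl12 is that alternatively activated macrophages were fewer. In 10 other genes of such macrophages the list mean differed by -0.0327 (exact two-sided permutation p = 0.8, over 4 lists tested adjusted p = 0.8), which leaves this open. If the laminin-332 chains were part of a wider change of epithelial anchorage, its receptors and hemidesmosome genes might have moved with them. The mean of Itga6, Itgb4, Col17a1, Dst, Cd151 and Itga3 differed by 0.0380 with an upper 95% bound of 0.131, but this list leaves out Itga2, which was higher, so the question stays open. If loss of cytotoxic cells were the source of lower Gzmf and Prf1, the other granzymes of the cluster could be lower too. The mean of 5 of them differed by -0.682 (exact two-sided permutation p = 0.171, adjusted p = 0.343), and all 5 were lower, but the spread between nonirradiated tumors leaves it open.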
